A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

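Ribosome-depleted total RNA from Saccharomyces cerevisiae was sequenced from 4 libraries, 2 from a strain lacking DBP2 (called dbp2null) and 2 from wild type, each grown at 30 °C in rich glucose medium to early log phase. The series' design text calls the second library of each genotype a biological replicate. Per the labels' protocols, the library steps were changed to retain short RNAs such as snoRNAs. The strains also differ in auxotrophy markers, so genotype at DBP2 and strain background cannot be separated by this design.

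The deposited values are FPKM, fragment numbers scaled by feature length and by the mapped fragments of the library, in one table with a column for each library. Per the submitters' processing notes, the authors named CASAVA, TopHat, Cufflinks and edgeR and the build sacCer3, with no order or role, and the tool versions are not given in the sources used here. The FPKM table from the authors holds no counts. Whole-read steps were looked for among low values after scaling by length. Between 8.4% and 13% of the 500 values checked per library lay within 0.05 of a whole multiple of the step tried. By chance 10% would. The step tried was 5.01 and 6.22 in dbp2null replicates 1 and 2 and 1.61 and 0.505 in wild type. The lowest scaled values were 0.679, 0.608, 0.317 and 0.0523, so that step may span several reads. The check therefore cannot show whether whole-read steps exist. Depth per library is unknown here and no counting interval can be given. The table has 7126 features after 3 blank rows were left out, of which 6169 were matched by name to the RefSeq annotation of the R64 assembly. The 957 unmatched features, 276 of them tRNAs, have no position here. In total 340 features are listed at 0 in all 4 libraries, including all 55 mitochondrial features. Since an exact 0 in such a table can be a failed estimate, features at 0 are described as listed at 0, with each library's value.

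FPKM was compared on the log2(FPKM + 1) scale, so fold changes of weakly expressed genes are understated. The 6781 features with a mean of at least 1 FPKM were fitted with limma 3.58.1 in R 4.3.3, with a mean-variance trend, no covariate and two-sided tests, and p-values were adjusted by the Benjamini-Hochberg method. Features with an adjusted p below 0.05 are called changed. With 2 libraries per genotype an exact permutation test cannot give a p below 0.333, so all tests rest on limma's spread pooled across features.

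Gene lists were written before the data were examined and tested with camera at an inter-gene correlation of 0.01, for lists with at least 5 tested members, with adjustment over the 36 lists tested. Members are counted as called over all features and as adjusted over the list alone. List medians are given relative to the median of all tested features. The lists cover tRNA, snoRNA, snRNA, other non-coding RNA and rRNA spacer features, Sen1, termination and exosome factors, R-loop factors, DEAD-box helicases, Nrd1-attenuated genes, ribosomal proteins and ribosome biogenesis, intron-containing genes, genes within 1000 bases downstream of a snoRNA gene on the same strand, carbon, phosphate, iron, sulfur, lysine, purine and amino acid metabolism, stress, chaperones, histones, cell wall, septum, flocculins, cell-wall mannoproteins of the PAU, DAN and TIR families, subtelomeric COS and YRF1 genes, respiration, pheromone response, mating-type, haploid and meiotic genes. Lists for retrotransposons and the 2 micron plasmid matched no feature by name. The list for cryptic transcripts matched only the sterol regulators SUT1 and SUT2 and was not tested. The list for mitochondrially encoded genes had no feature above 0. Ty transposon reading frames, 77 of them among the tested features, were found by annotated product after the data were seen and not tested as a list.

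Named genes follow a rule set before the data were examined: DBP2 and the marker genes; the 12 largest rises and falls among called features with a mean of at least 10 FPKM and both dbp2null values on one side of both wild-type values; up to 3 members per direction of each list with a camera call or at least 2 called members; and up to 4 members of the lists of non-coding RNAs, Sen1 and R-loop factors and helicases. Features without a gene name were passed over beyond 2 per direction. From these the text gives examples.

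Alternatives set before the data were examined were pseudocounts of 0.1 and 5, no filter, a mean of at least 10 FPKM, median centring, quantile normalization, nuclear protein-coding features rescaled to one sum, no trend, the replicate number as a block, each library left out, a doubling or halving as an added threshold, an adjusted p below 0.1, camera with an estimated correlation, fry, and a window of 500 bases. Alternatives added after the data were seen were features above 0 in every library, features of at least 300 bases, subtraction of a background level, the block with crossed numbers, and intron-containing genes outside the ribosomal protein list. The background level was each library's median FPKM over the meiotic list. After subtraction the libraries were rescaled to a common median log2 level over protein-coding features of at least 50 FPKM in every library. Background subtraction stands for both steps together, and their effects were not separated. A count test on recovered whole reads was not run because no whole reads were recovered. Near-identical copies were found with blastn 2.17.0 as genome matches of at least 95% identity over at least 80% of a feature.

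The procedure was tested on simulated data for the comparison of dbp2null with wild type, with 6781 features of which 200 were changed by known amounts, 50 at each size, and another 20 were shifted together as a list. It recovered 6 of 50 changed by 1 on the log2 scale, 34 of 50 changed by 2, 40 of 50 changed by 3 and 43 of 50 changed by 4, with 14 false calls among 6561 unchanged features. Camera called 0 of 30 unshifted lists and called the shifted one (adjusted p = 6.47e-23). Noise was drawn independently for each feature, with the same spread in both genotypes, so genes that vary together were not simulated. The 0 of 30 is therefore no check on camera for the real lists. Changed features were drawn only from those of higher mean level, so recovery among weakly expressed ones was not measured.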

Results

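RNA levels were measured in 2 dbp2null and 2 wild-type libraries of budding yeast to ask how the transcriptome differs when the DEAD-box RNA helicase Dbp2 is absent. The series' title links the protein to non-coding RNAs, the helicase Sen1 and R-loops. FPKM summed to 5.01e+07 and 3.37e+06 over the dbp2null libraries, replicates 1 and 2, and to 5.29e+07 and 3.22e+07 over the wild-type libraries. On the log2 scale the wild-type libraries correlated with r = 0.97 across 6781 features and the dbp2null libraries with r = 0.81, with SDs of the difference of 0.71 and 1.56. Features are not replicates, so these values are descriptive. Read depth is unknown.

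DBP2 (YNL112W, chromosome XIV, 413639 to 416281, R64 assembly) was nearly absent from the mutant. It stood at 2.90 and 1.03 FPKM in the dbp2null libraries and at 213 and 199 FPKM in wild type, a fall of log2 fold change -6.20 (SE 0.35, limma adjusted p = 0.0225), a call that ended without either wild-type library (adjusted p = 0.0849 without replicate 1 and 0.10015 without replicate 2). Of the auxotrophy markers, LYS2, needed for lysine synthesis, fell from 37.8 and 31.7 FPKM to 1.63 and 0.679 FPKM, as the lysine-requiring genotype in the mutant's label has it. MET17, also called MET15 and deleted in the wild-type label, rose from 0.237 and 0.422 FPKM to 31.5 and 22.5 FPKM. The LYS2 call ended in 11 and the MET17 call in 9 of 17 alternatives. URA3 stood at 3.52 and 1.39 FPKM in dbp2null and 0.396 and 0.317 FPKM in wild type, and LEU2 stayed below the filter. HIS3 read 80.4 and 73.7 FPKM in dbp2null and 60.9 and 78.9 FPKM in wild type, although the mutant's label gives a full deletion, and TRP1 did not pass the test (95.3 and 74.8 against 62.9 and 70.4 FPKM). Next to DBP2, NOP15, CYB5, RPC19 and YNL115C did not pass the test, with log2 fold changes of -0.16, -1.42, -0.91 and 1.18.

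Apart from the marker MET17, the largest rises among called genes with a gene name, a mean of at least 10 FPKM and values above 0 in every library were those of YRO2, THI4 and RRT5. YRO2, a plasma membrane protein gene, rose from 17.9 and 15.3 FPKM to 166 and 136 FPKM (log2 fold change 3.11, SE 0.22, limma adjusted p = 0.0415). THI4, for thiamine synthesis, rose by 3.02, RRT5 by 2.96, PHM8, a phosphatase gene, by 2.90, SPI1, a cell wall protein gene, by 2.74, GCV1 of the glycine cleavage system by 2.68, HSP26, a small heat shock protein gene, by 2.66, YPC1, a ceramidase gene, by 2.59 and NCA3 by 2.57, with SEs between 0.21 and 0.33. ANB1, a translation factor gene best known for expression without oxygen, fell from 77.0 and 93.8 FPKM to 11.2 and 12.8 FPKM. VTC3, a polyphosphate synthesis gene, fell from 113 and 103 FPKM to 20.9 and 22.3 FPKM. TLC1, the telomerase RNA, fell from 128 and 135 FPKM to 27.6 and 32.0 FPKM (log2 fold change -2.11, SE 0.22, limma adjusted p = 0.0465). These 12 genes kept their direction in every alternative that tested them, but their calls lie close to the threshold. Without a wild-type library, the spread in the test comes only from the dbp2null pair, which differed more than the wild-type pair. All 12 calls ended without wild-type replicate 1 or 2 (limma adjusted p from 0.0996 to 0.385), with a pseudocount of 0.1, without the trend, with quantile normalization and with background subtraction, and 9 ended without dbp2null replicate 2, 9 with median centring, 8 with the replicate block, 8 with a mean of at least 10 FPKM and 7 of 11 with protein-coding rescaling. The size moved by over 1.5 times for VTC3 with that rescaling (-1.46, limma adjusted p = 0.58) and for RRT5 with quantile normalization (1.90, adjusted p = 0.127). It also did for THI4, ANB1 and VTC3 with background subtraction, which also rescales the libraries (4.67, -6.06 and -3.41).

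**Figure D1:**
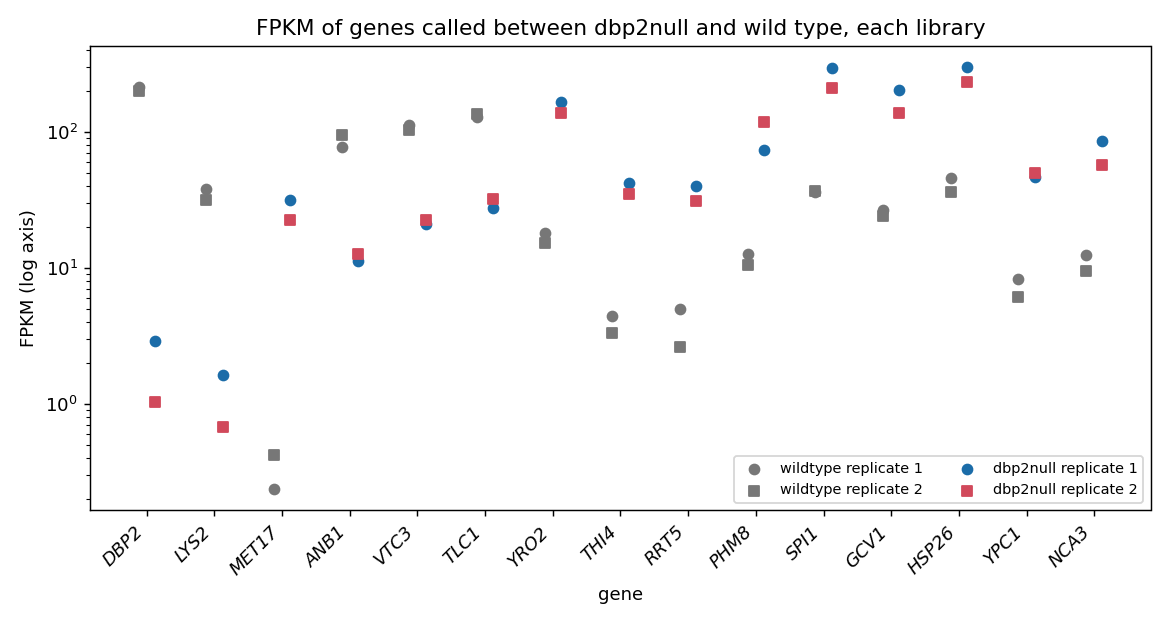
FPKM (log axis) of 15 genes called between dbp2null and wild type, with 1 point per library. For each gene both dbp2null points lie on one side of both wild-type points, as for DBP2 at 2.90 and 1.03 against 213 and 199 FPKM.

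In all, 81 of 6781 features were called, 66 higher and 15 lower in dbp2null. Of these, 46 were above 0 in every library, 41 higher and 5 lower. The other 35 are listed at 0 in both libraries of one genotype. Of the 23 with a position, 21 have a near-identical copy elsewhere in the genome, against 279 of 6071 tested features. Ty transposon reading frames listed at 0 in both wild-type libraries make up 18 of the 23, with 77 Ty frames tested. This class was picked out after the data were seen. YLR159C-A, beside the rDNA and with 6 matches in the genome, is listed at 0 in both dbp2null libraries and at 1106 and 311 FPKM in wild type. The snoRNA snR190 is listed at 0 in both dbp2null libraries and at 607853 and 862207 FPKM in wild type. YBR126W-B is likewise at 0 in dbp2null, while YFL032W and YGR265W are at 0 in wild type and at 567 and 266 and at 144 and 90.03 FPKM in dbp2null. At an unadjusted p below 0.05 there were 2568 features, 2201 of them higher. In 70.5% of features both dbp2null values lay on one side of both wild-type values. Without ties, the average over all splits of the libraries into pairs is 33.3%. Features share library-wide shifts, so the excess over that average is not a test. The median log2 fold change of all tested features was 0.28, and rescaling to protein-coding features moved it to 1.14, so list medians are given relative to it. The split of 66 higher and 15 lower became 3 and 10 with median centring and 1 and 4 with quantile normalization. It became 6 and 10 with the replicate number as a block and 2 and 6 with a pseudocount of 0.1. With a mean of at least 10 FPKM it was 4 and 9. As chosen after the data were seen, it was 2 and 3 with background subtraction, which also rescales the libraries. More were higher with a pseudocount of 5 (380 and 45), no filter (68 and 15), no trend (29 and 12) and protein-coding rescaling (45 and 12), and, in settings chosen after the data were seen, among features above 0 in every library (1119 and 79), among those of at least 300 bases (1772 and 334) and with the pairing crossed (2454 and 213). Without dbp2null replicates 1 and 2 in turn limma called 2512 (1073 higher and 1439 lower) and 90 features (58 higher and 32 lower), and without wild-type replicates 1 and 2 it called 0 and 6, all 6 lower, with 1423 and 854 at an unadjusted p below 0.05.

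Environmental stress genes were higher as a group in dbp2null. The median of 28 members lay 0.96 above that of all features (camera adjusted p = 9.77e-05, adjusted p = 0.657 with an estimated correlation). Of these, 4 rose over all features and 20 adjusted over the list alone, among them GSY2, glycogen synthase (51.1 and 49.8 against 16.3 and 16.6 FPKM), and DCS2 (39.6 and 39.1 against 10.4 and 10.04 FPKM), whose calls each ended in 11 of 17 alternatives. Glucose transporter genes were higher as a group (relative median 1.09, camera adjusted p = 0.0253, adjusted p = 0.657 with an estimated correlation), with 9 members higher and 3 lower. The 3 were HXT3 (133 and 201 against 157 and 192 FPKM), HXT2 (60.2 and 41.3 against 51.8 and 52.7 FPKM) and HXT1 (24.4 and 42.0 against 42.6 and 46.4 FPKM). The near-identical HXT6 and HXT7, which can share reads, were the 2 of 12 called, each losing its call in 11 of 17 alternatives, and the camera call ended without dbp2null replicate 2 (relative median 0.83, adjusted p = 0.185) and with protein-coding rescaling (1.02, adjusted p = 0.0774). Glucose-repressed genes were higher (relative median 1.501, camera adjusted p = 0.007, adjusted p = 0.657 with an estimated correlation), with 0 of 14 called over all features and 12 higher and 1 lower adjusted over the list alone. Without dbp2null replicate 2 the relative median was 0.95, still with a camera call (adjusted p = 0.0305). With all 4 libraries the call ended with a mean of at least 10 FPKM (1.21, adjusted p = 0.0529), protein-coding rescaling (1.397, adjusted p = 0.162), quantile normalization (0.36, adjusted p = 0.436) and, as chosen after the data were seen, background subtraction (0.80, adjusted p = 0.433). The lactate transporter gene JEN1 read 22.7 and 40.3 against 7.26 and 5.88 FPKM, while the alcohol dehydrogenase gene ADH2 read lower, 48.3 and 40.6 against 129 and 193 FPKM. Genes silent in wild type also read higher, with medians of 11.3 and 19.5 against 4.29 and 2.77 FPKM. POT1 of this list lay near that level (15.3 and 18.5 against 4.97 and 3.61 FPKM), while JEN1 and ADH2 lay above it. How far that raised level carries the list was not tested beyond background subtraction.

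Glycolysis and fermentation genes were lower, with a relative median of -1.91 over 19 members (camera adjusted p = 8.64e-07, adjusted p = 0.657 with an estimated correlation). None was called over all features, and 7 fell and 1 rose adjusted over the list alone. With quantile normalization the relative median was -0.54 and the camera call ended (adjusted p = 0.292). The hexokinase gene HXK2 read 111 and 97.2 against 506 and 513 FPKM, PGK1, phosphoglycerate kinase, 445 and 267 against 1605 and 1703 FPKM, and HXK1, the other hexokinase gene, was higher at 56.2 and 65.2 against 23.6 and 16.4 FPKM. Phosphate genes were lower (relative median -0.88, camera adjusted p = 0.00109, adjusted p = 0.657 with an estimated correlation). VTC3 fell and PHM8 rose over all features, and 8 of 18 fell and 4 rose adjusted over the list alone, with SPL2 at 19.2 and 29.3 against 103 and 86.5 FPKM, VTC4 at 43.7 and 44.4 against 147 and 136 FPKM and PHO89 at 24.6 and 43.6 against 8.49 and 5.74 FPKM. The camera call ended without dbp2null replicate 1 (relative median -0.64, adjusted p = 0.222). Amino acid genes under Gcn4 were lower (relative median -0.67, camera adjusted p = 0.000159), as were purine genes (-0.73, camera adjusted p = 0.00225), both with an adjusted p = 0.657 with an estimated correlation. Adjusted over the list alone, 1 of 25 amino acid genes rose and 1 fell, and 3 of 10 purine genes fell. The purine call ended with quantile normalization (-0.24, adjusted p = 0.179), protein-coding rescaling (-0.78, adjusted p = 0.14) and background subtraction (-0.37, adjusted p = 0.154). HIS4 read 27.5 and 34.0 against 84.7 and 75.1 FPKM, HIS1 162 and 113 against 538 and 543 FPKM, and ADE12 44.1 and 33.2 against 89.4 and 94.1 FPKM. Chaperone genes went both ways, with a relative median of -1.19 (camera adjusted p = 0.0019, adjusted p = 0.657 with an estimated correlation) that became -0.31 with quantile normalization, without a call (adjusted p = 0.604). Adjusted over the list alone, 9 of 26 fell, among them the mitochondrial HSP60 (91.9 and 72.1 against 300.1 and 287 FPKM) and HSP82 (61.1 and 66.0 against 162 and 148 FPKM), and 6 rose, among them HSP42 (73.6 and 78.3 against 27.3 and 20.1 FPKM).

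Non-coding RNA classes split between the dbp2null libraries. tRNA features were lower by camera (272 members, relative median -2.82, adjusted p = 5.23e-19, adjusted p = 0.657 with an estimated correlation), with 0 called, but the median log2 fold change was 0.10 in dbp2null replicate 1 alone and -5.24 in replicate 2 alone. Relative to all features, whose median in replicate 1 alone was 0.37, the tRNA median was still -0.28 without dbp2null replicate 2. It was -5.46 without replicate 1. With quantile normalization the tRNA value was -1.45, still with a camera call (adjusted p = 3.58e-06). The 76 snoRNA features gave a relative median of -1.63 (camera adjusted p = 2.86e-07, adjusted p = 0.657 with an estimated correlation), with medians of 0.44 and -3.16 in replicates 1 and 2 alone, and the relative median turned to 0.07 without dbp2null replicate 2 (adjusted p = 0.439) and 0.08 with quantile normalization (adjusted p = 0.433), against -3.38 without replicate 1. Among features of at least 300 bases the snoRNA value was -0.64, without a call (adjusted p = 0.123). Only snR190 was called. With both libraries, 15 of the 76 had a positive and 61 a negative log2 fold change. The snoRNAs snR57 (289 and 43.0 against 1240 and 2463 FPKM) and snR59 (492 and 16.7 against 2312 and 2580 FPKM) read lower. By contrast, snR85 read higher (308298 and 119226 against 72277 and 73219 FPKM). None of these 3 passed the test. ICR1, a long non-coding RNA upstream of FLO11, read 11.8 and 21.4 against 4.18 and 4.02 FPKM without a call. These values lie near the medians of genes silent in wild type (11.3 and 19.5 against 4.29 and 2.77 FPKM). snRNA, rRNA spacer and other non-coding RNA lists had no camera call (adjusted p = 0.366, 0.125 and 0.151), although the rRNA spacer list was called higher with quantile normalization (1.34, adjusted p = 0.0141). Genes downstream of snoRNA genes had no camera call (32 members, relative median -0.12, adjusted p = 0.319). The value was -0.28 without dbp2null replicate 2 (adjusted p = 0.086) and -0.20 with quantile normalization (adjusted p = 0.0549).

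Sen1, termination and exosome genes (17 members, relative median -0.11, camera adjusted p = 0.41), R-loop factors (15 members, -0.07, adjusted p = 0.475) and Nrd1-attenuated genes (7 members, -0.32, adjusted p = 0.126) had no camera call, and no member was called over all features. Without dbp2null replicate 2 the Nrd1-attenuated list was called lower (-0.61, adjusted p = 0.0235), and the R-loop and Sen1 lists lay at -0.29 and -0.37 without a call (adjusted p = 0.27 and 0.167). Without dbp2null replicate 1 the Nrd1-attenuated, R-loop and Sen1 lists lay at -0.057, -0.015 and 0.11, also without a call (adjusted p = 0.656, 0.902 and 0.936). The exosome cofactor gene LRP1 read 54.3 and 55.3 against 35.4 and 26.8 FPKM, HRP1, for an RNA-binding protein of 3′ end formation, 64.1 and 48.4 against 109 and 88.2 FPKM, and MFT1 of the THO complex 24.8 and 43.3 against 15.4 and 10.6 FPKM. DEAD-box helicase genes lay on both sides of wild type. By camera the list was slightly lower than other features (25 members, relative median -0.33, adjusted p = 0.0407, adjusted p = 0.699 with an estimated correlation), with a median log2 fold change of -0.05, 11 members higher and 14 lower, and 0 called. SUB2 read 163 and 93.7 against 385 and 417 FPKM and DBP5 84.3 and 66.3 against 156 and 142 FPKM, while PRP5 read 18.2 and 30.2 against 10.2 and 7.10 FPKM. That camera call ended in 8 of 17 other settings, with an adjusted p between 0.0543 and 0.259 and relative medians between -0.39 and -0.16. Among them, leaving out dbp2null replicate 1 (-0.33, adjusted p = 0.151) or wild-type replicate 1 (-0.31, adjusted p = 0.123) left the median nearly as it was.

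Ribosomal protein genes were lower as a group, with 136 of 137 below wild type, a relative median of -1.52 and 0 called (camera adjusted p = 1.52e-15, adjusted p = 0.657 with an estimated correlation), a direction that turned to 0.35 with quantile normalization. Their median log2 fold change was -0.52 in dbp2null replicate 1 alone and -1.91 in replicate 2 alone. RPL18B read 239 and 134 against 667 and 785 FPKM. Ribosome biogenesis genes were lower (85 members, relative median -0.50, camera adjusted p = 4.01e-07, adjusted p = 0.657 with an estimated correlation), but the relative median was -0.0046 with quantile normalization (adjusted p = 0.604) and -0.14 with background subtraction (adjusted p = 0.384), and the call also ended with protein-coding rescaling (-0.56, adjusted p = 0.0513). Intron-containing genes were lower (269 members, relative median -0.77, camera adjusted p = 2.51e-05, adjusted p = 0.657 with an estimated correlation), a direction that turned to 0.18 with quantile normalization. Their median log2 fold change was -0.05 in dbp2null replicate 1 alone and -0.98 in replicate 2 alone, and the relative median was -0.42 without replicate 2 and -1.21 without replicate 1, with a camera call in both (adjusted p = 9.21e-06 and 5.93e-08). Of the 269, 89 are ribosomal protein genes, and the other 180 missed the threshold (relative median -0.27, adjusted p = 0.0941). Histone genes were lower (10 members, relative median -1.23, camera adjusted p = 0.0019, adjusted p = 0.657 with an estimated correlation). Their medians were -0.18 and -1.81 in dbp2null replicates 1 and 2 alone, and 0.54 relative to all features with quantile normalization. Among protein-coding features with at least 100 FPKM in dbp2null replicate 1, the log2 ratio of replicate 2 to 1 fell with shorter length. Its median was -2.31 at up to 300 bases and -0.58 over 1000 bases. The relative medians without dbp2null replicate 2 were -0.89 for ribosomal protein and -0.55 for histone genes. How far length carries either fall was not tested.

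Subtelomeric COS and YRF1 genes were higher in dbp2null, all 20 members (relative median 1.43, camera adjusted p = 1.64e-06, adjusted p = 0.657 with an estimated correlation). COS1 rose over all features (49.1 and 56.9 against 15.3 and 15.4 FPKM), a call that ended in 11 of 17 alternatives, and all 20 rose adjusted over the list alone, although 14 have near-identical copies. Flocculin genes (6 members, relative median 2.13, camera adjusted p = 0.0234) and meiotic genes (15 members, 1.37, camera adjusted p = 0.00108) were also higher, both with an adjusted p = 0.657 with an estimated correlation. Adjusted over the list alone, 6 of 6 flocculin and 13 of 15 meiotic genes rose, and the flocculin call ended without dbp2null replicate 2 (1.298, adjusted p = 0.0867), with quantile normalization (1.25, adjusted p = 0.0582) and with background subtraction, where the relative median was 2.85 (adjusted p = 0.0708). The meiotic call ended with quantile normalization (0.32, adjusted p = 0.33). FLO10 read 16.5 and 63.1 against 4.40 and 1.64 FPKM and NDT80, the meiotic transcription factor gene, 24.4 and 31.7 against 9.52 and 8.72 FPKM. Meiotic genes, silent in haploid cells, had a median of 11.8 and 18.7 FPKM in the dbp2null libraries and of 4.13 and 3.80 FPKM in wild type. This level was the one subtracted as background, so the meiotic list itself was not read after subtraction. In dbp2null replicate 1, FLO10, FLO9 and FLO5 lay near the meiotic median (16.5, 14.6 and 13.1 FPKM). In replicate 2 they lay above it (63.1, 43.8 and 35.3 FPKM).

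**Figure D2:**
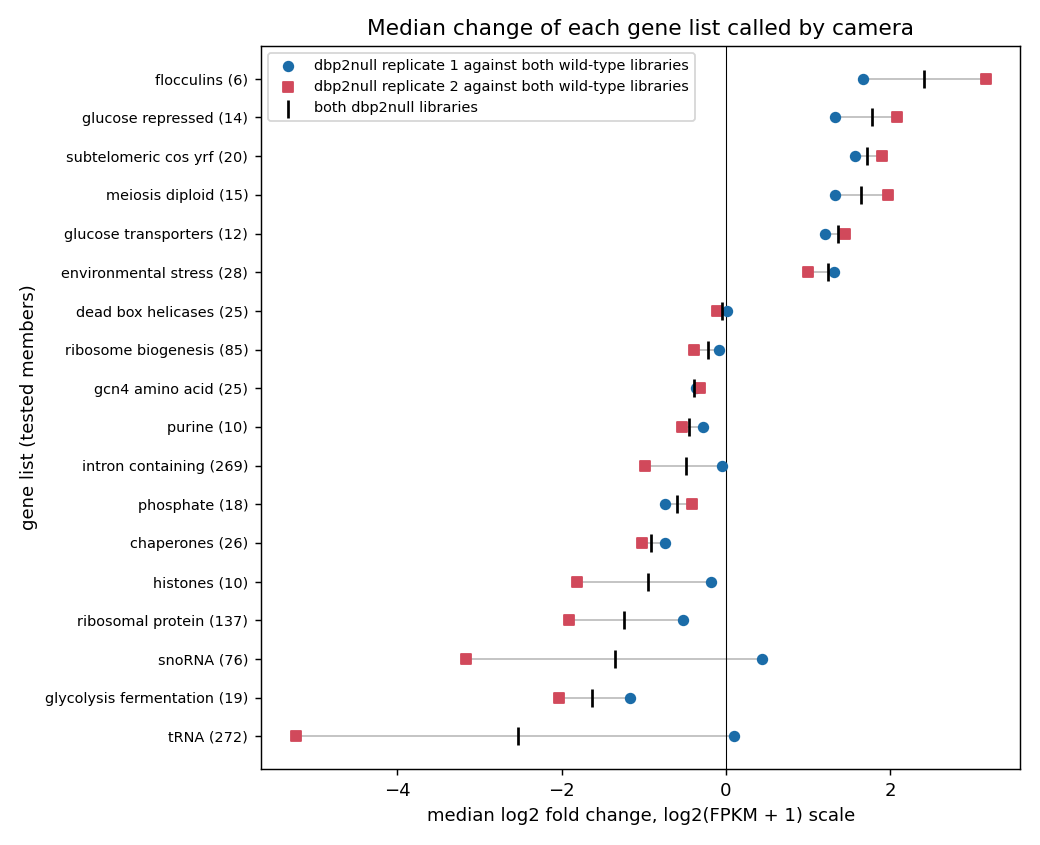
Median log2 fold change (log2(FPKM + 1) scale, not relative to all features) of the 18 gene lists called by camera, with tested members in brackets. Circles and squares set dbp2null replicates 1 and 2 alone against both wild-type libraries, and bars give both together; tRNA and snoRNA medians lie at 0.10 and 0.44 in replicate 1 and at -5.24 and -3.16 in replicate 2.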

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

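Background subtraction, the limits to features above 0 and to at least 300 bases, the crossed pairing and the split of intron-containing genes were chosen after the data were seen. The count of 81 changed features was 8 and 425 with pseudocounts of 0.1 and 5, 13 with a mean of at least 10 FPKM, 13 with median centring, 5 with quantile normalization, 41 without the trend and 2102 at an adjusted p below 0.1. With 1 library left out it ranged from 0 to 2512, where the lone library of a genotype is assumed to vary like the others. The labels share replicate numbers. The difference between replicates 1 and 2 in dbp2null correlated with that in wild type at -0.11 across the 6781 features, which are not replicates. With the replicate block 16 features were called, and with the pairing crossed 2667. Among features above 0 in every library 1198 were called, among those of at least 300 bases 2106, and after background subtraction 5. With 1 library left out, the spread within a genotype comes only from the other genotype's pair. The SD of the difference was 1.56 for the dbp2null pair and 0.71 for the wild-type pair. Calls without a wild-type library therefore rest on the wider dbp2null spread, and calls without a dbp2null library on the narrower one. These SDs also put the test's assumption of equal spread in doubt. The cause of the other shifts was not tested, beyond fewer features tested. DBP2 stayed lower in every setting, from -6.67 to -5.73 with 1 library left out, but missed the threshold with a pseudocount of 0.1 (log2 fold change -6.81, adjusted p = 0.064) and without either wild-type replicate 1 (-6.15) or 2 (-6.25).

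Of 36 lists, 18 were called, 8 with quantile normalization and 0 with an estimated correlation (smallest adjusted p = 0.657), fry or fry with the replicate block. The intron-containing value of -0.77 missed the threshold with an estimated correlation, was -0.27 outside the ribosomal protein list and 0.18 with quantile normalization. With quantile normalization the relative medians also turned to 1.499 for snRNA, 0.28 for other non-coding RNA, 0.57 for respiration, 0.0065 for iron, 0.22 for septum, 0.54 for histone, 0.082 for snoRNA, 1.34 for rRNA spacer and 0.35 for ribosomal protein genes, and URA3 to -0.51. With 1 library left out they ranged from -1.70 to 1.11 for snRNA, -0.66 to 0.43 for respiration, -3.38 to 0.069 for snoRNA and -1.81 to 0.25 for rRNA spacer (each lowest without dbp2null replicate 1 and highest without replicate 2), from -0.37 to 0.11 for Sen1 factors and from -0.18 to 0.048 for septum. Background subtraction turned Sen1 factors to 0.026, R-loop factors to 0.026, snRNA to 0.59, other non-coding RNA to 0.014, respiration to 0.33, iron to 0.039, septum to 0.27 and rRNA spacer to 0.36. A mean of at least 10 FPKM turned septum to 0.0097, protein-coding rescaling HRP1 to 0.0092, and HIS3 became -0.19 with median centring and ranged from -0.034 (without wild-type replicate 1) to 0.33 with 1 library left out. The cause was not tested.

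Replicate correlations of 0.81 (dbp2null) and 0.97 (wild type) became 0.75 and 0.94 with a pseudocount of 0.1, 0.85 and 0.98 with 5, 0.84 and 0.96 with quantile normalization, 0.88 and 0.98 for protein-coding features, 0.88 and 0.99 above 0 in every library and 0.90 and 0.98 at 300 bases or more; background subtraction gave 0.78 for dbp2null. Depth is unknown, so its limit on low values cannot be given.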

Other observations

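Other lists had no camera call with all 4 libraries and the values as deposited. Respiration genes had a relative median of -0.22 (46 members, adjusted p = 0.35), with median log2 fold changes of 0.81 and -0.43 in dbp2null replicates 1 and 2 alone. They were called lower without dbp2null replicate 1 (-0.66, adjusted p = 0.00443) and with protein-coding rescaling (-0.27, adjusted p = 0.0251), and called higher without replicate 2 (0.43, adjusted p = 0.000152), with quantile normalization (0.57, adjusted p = 8.11e-05) and with background subtraction (0.33, adjusted p = 0.00828). Lysine (-0.82, adjusted p = 0.0658), iron (-0.15, adjusted p = 0.419), septum (-0.02, adjusted p = 0.575), haploid (-0.31, adjusted p = 0.215) and a-specific genes (-1.19, adjusted p = 0.117) lay below all features. Galactose (1.24, adjusted p = 0.0951), PAU, DAN and TIR (0.51, adjusted p = 0.0854), pheromone (1.14, adjusted p = 0.164), cell wall (0.31, adjusted p = 0.309) and sulfur genes (0.40, adjusted p = 0.372) lay above. Some were called in the same direction elsewhere: a-specific genes with protein-coding rescaling (-1.24, adjusted p = 4.32e-07), lysine genes without dbp2null replicate 2 (-0.83, adjusted p = 0.00947), with median centring (adjusted p = 0.0457) and at 300 bases or more (adjusted p = 0.025), galactose genes without dbp2null replicate 1 (1.74, adjusted p = 0.0394) and without wild-type replicates 1 and 2 in turn (adjusted p = 0.0489 and 0.0251), PAU, DAN and TIR and pheromone genes without dbp2null replicate 1 (adjusted p = 0.0105 and 0.0427), and cell wall genes with protein-coding rescaling and background subtraction (adjusted p = 0.042 and 0.0101). With 1 library left out the relative medians ranged from -1.43 to -0.36 for a-specific genes, -0.56 to -0.10 for haploid, 0.23 to 0.62 for sulfur, 0.71 to 1.74 for galactose, 0.65 to 1.59 for pheromone and 0.27 to 0.66 for PAU, DAN and TIR genes. In each of these the value nearest 0 was without dbp2null replicate 2 and the farthest without replicate 1. Cell wall genes ranged from 0.067 without dbp2null replicate 1 to 0.37 without wild-type replicate 2, and iron genes from -0.28 without wild-type replicate 1 to -0.023 without wild-type replicate 2. Alpha-specific genes had only 4 tested members, and STE3, for the a-factor receptor, read 5.47 and 15.5 against 4.54 and 2.69 FPKM.

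All tests below except those on subtelomeric genes were chosen after the result was seen, and their thresholds are choices of this re-analysis. Genes silent in wild type read higher in dbp2null. They were taken as 153 single-copy protein-coding genes of at least 1000 bases, above 0 in every library, with a wild-type mean below 5 FPKM. Their medians were 11.3 and 19.5 FPKM in dbp2null and 4.29 and 2.77 FPKM in wild type. Choosing genes by a low wild-type mean fixes part of that difference, and caps their spread in wild type; the meiotic list, fixed before the data were examined, had medians of 11.8 and 18.7 FPKM against 4.13 and 3.80 FPKM. A constant added to every feature is argued against, since it would also raise the 4 deleted genes DBP2, LYS2, LEU2 and URA3. These reached at most 1.395 FPKM in dbp2null replicate 2. The lowest of the 153 silent genes read 7.17 FPKM there, but silent genes listed at 0 in any library had been left out. HIS3, which reads 73.7 FPKM in that library despite its label, was left out of the 4 deleted genes. An even background over the genome, such as DNA in the library, may contribute but was not decided: the 90th to 10th percentile ratio of these genes was 2.781 in dbp2null replicate 2, between the 1.99 and 3.27 of the wild-type libraries. Loss of DBP2 and library background cannot be told apart here, as the dbp2null medians differed 1.732-fold and the wild-type medians 1.55-fold, with 1 ratio per genotype.

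tRNA and snoRNA features were lower in dbp2null replicate 2. Without it, the tRNA median log2 fold change was 0.10, not below wild type, while the median of all features was 0.37. The relative medians were therefore -0.28 for tRNA and 0.07 for snoRNA, against -2.82 and -1.63 for both libraries. Poor recovery of short features in replicate 2 is a candidate explanation. Protein-coding features with at least 100 FPKM in replicate 1 were compared by length. The log2 ratio of replicate 2 to 1 had a median of -2.31 for 194 of at most 300 bases. For 272 over 1000 bases it was -0.58, a difference of -1.731. In the same features the wild-type libraries gave 0.02 and -0.03. Choosing features by a high replicate 1 value can itself lower this ratio, and the wild-type ratio carries no such selection. How much of the difference comes from that choice was not measured. Poor recovery in replicate 2 does not cover the tRNA relative median without that library, which is not a fall below wild type. An effect of DBP2 on either class stays open.

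Subtelomeric genes may differ for a reason beyond the raised level of silent genes. Single-copy genes above 0 in every library were compared. The 254 within 30000 bases of a chromosome end lay 0.5277 (log2, median) above internal genes of the same wild-type level. The 95% bootstrap interval was 0.43 to 0.58 (permutation test over genes, two-sided, p = 1e-05, the smallest 100000 resamples can give). Genes share the same libraries and are not replicates, so the interval and p measure spread over genes, not between libraries. For these libraries, the excess argues against an even background and against reads shared between near-identical copies as the whole cause. With dbp2null replicate 1 alone the excess was 0.36. Strain differences at chromosome ends and loss of DBP2 were not separated by the design and stay open, untested.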
